A study of Mus musculus with 2 samples.

How the data were processed

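H3K4me2 was measured by ChIP-seq in hearts pooled from male and female mouse embryos of embryonic day 14.5, in 2 biological replicates of 1 group. The labels name a control experiment, which is not part of the series. The deposited files are 4 peak lists on mm10: the list of each replicate, a pooled list called on both replicates' alignments together, and a replicated list. Per the labels of the files, replicate 1's list was made from its alignment and 2 further input files, and replicate 2's from its alignment and 1 further input file. The role of these inputs, the peak caller and its threshold are not given in the sources used here.

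Each list is in narrowPeak format. The deposited score is a display score that rescales the authors' −log10 p linearly within a list, as tested on the values. The deposited signal value is the authors' enrichment value per peak, and its scale is not stated, so it was used only to describe, rank or compare peaks within a list. The authors' −log10 p and −log10 q per peak were taken as deposited, and the first ranked peaks for the better-scoring 50%. The lowest deposited −log10 p was 2.00 in replicate 1's list and 2.05 in replicate 2's. Read counts were not used here, so the depth of each library is unknown and no counting interval was given for peaks.

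Gene models were from GENCODE M21 and the sequence from GRCm38.p6, which is mm10. The canonical transcript was that with the best APPRIS level, then the longest coding sequence. Where 27 symbols belonged to more than 1 gene, the first by position was used, which left 21911 of 21938 protein-coding genes. A gene was called marked when a replicated peak lay within 1 kb of its canonical start site. Covered length was the number of bases under replicated peaks within 5 kb of the start site. Distal covered length was counted within 50 kb, without bases within 2.5 kb of any protein-coding start site. Promoter CpG content was the observed to expected CpG ratio within 500 bp of the start site, in deciles. Coordinates are printed counting from 1.

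A total of 21 gene lists was fixed before the data were examined: cardiac transcription factors, sarcomere genes, genes of calcium handling, ion channels and natriuretic peptides, signalling genes of heart development, markers of endothelium and endocardium, epicardium, fibroblasts and valve mesenchyme, smooth muscle and pericytes, neural crest with Schwann cells and autonomic neurons, erythroid cells, macrophages and immune cells, liver, forebrain and neurons, skeletal muscle, lung epithelium and kidney epithelium, and Hox, housekeeping, proliferation, mitochondrial energy metabolism and olfactory receptor genes. The erythroid gene Ahsp has no entry under that name in the annotation and was left out. Each list's median was placed among 10000 random lists matched on CpG decile, and called above or below them outside percentiles 2.5 to 97.5. This is a description and not a p-value, since genes are not replicates. The rule for named genes was fixed at the same time: in each list the 4 members with the longest covered length and up to 4 unmarked members in alphabetical order, any member of the first 3 lists, the 20 genes in the broadest domains, the 10 with the most distal coverage, the 10 strongest distal peaks, and the 5 strongest genes marked in each replicate alone.

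Peaks were counted as shared when the overlap reached 50% of either peak (bedtools 2.31.1), beside 100 circular shifts of the other list along each chromosome. Domains were replicated peaks merged within 1 kb. For 18 consensus motifs, 27326 distal domains were searched in a window of 500 bp around the midpoint on both strands. Control windows lay 5 kb up- or downstream of a domain, outside every deposited peak and over 2.5 kb from any protein-coding start site. Within each 5% bin of GC content, equal numbers of domains and controls were drawn at random, 22484 of each. A domain was thus not paired with its own neighbouring window. A motif was called when the exact binomial 95% intervals of both shares did not overlap. The spread between replicates is the SD of the values from each replicate's own list (n = 2).

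Alternatives were other overlap rules, the better-scoring 50% of peaks, the pooled list, windows of other sizes, starts of all transcripts, gene body coverage, other matching of random lists, controls without GC matching, whole distal peaks, autosomes only and each replicate's list alone. Windows under 10% repeat sequence were added after the motif results were seen. A paired analysis does not apply to 1 group. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with matplotlib 3.10.9 for figures.

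The code was tested on simulated data. Covered lengths matched a count base by base in 500 of 500 windows. A list with a planted overlap of 69.9% gave 70.2%. Of 200 unrelated gene lists 5% fell outside the random range, and 99% of 200 lists with raised values were recovered. A MEF2 match planted to raise the share by 19.1 points gave 19.4 points, and 0 of 17 unplanted motifs were called. The simulated gene values lacked the many values of 0 bp among covered lengths, and the simulated windows were random bases. The gene list and motif tests therefore check the code and not its calibration on the real data. Peaks on contigs outside the assembled chromosomes entered the overlap counts and no other comparison.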

Results

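H3K4me2, histone H3 dimethylated at lysine 4, lies on nucleosomes at promoters and enhancers. It was mapped by chromatin immunoprecipitation and sequencing in hearts of healthy mouse embryos of embryonic day 14.5, pooled from males and females. The series held 1 group of 2 biological replicates and no second tissue, stage or genotype. Replicate 1's list held 63243 peaks covering 63.0 Mb, which was 2.31% of the mm10 genome. Replicate 2's list held 56371 peaks covering 56.2 Mb, or 2.06%. A list called on both replicates together held 62586 peaks, and 50330 of these formed the authors' replicated list, which covered 63.1 Mb with a median peak width of 877 bp. The number of reads behind each list was not given in the files. Values below are from the replicated list, and each ± is the SD of the values from both replicates' own lists around their mean (n = 2). Since there was 1 group, no difference between groups was tested. A gene list was instead set beside 10000 random lists of the same size, matched gene by gene on promoter CpG content.

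The transcription factors that build the heart carried the longest H3K4me2 around their transcription start sites of the 21 gene lists. Gata4 and Gata6, zinc finger factors of heart muscle development, and Tbx5, the T-box factor mutated in Holt-Oram syndrome, were covered over the whole 10001 bp window centred on the start site. So was Hand2, a basic helix-loop-helix factor of the right ventricle. In the replicates' own lists the covered length was 10001 ± 0 bp at Gata4 and at Tbx5, 9969.5 ± 44.5 bp at Gata6 and 9941.5 ± 31.8 bp at Hand2. Tbx20 followed with 9850 bp (9748 ± 171 bp) and Nkx2-5, the homeodomain factor of cardiac precursors, with 9776 bp (9643.5 ± 44.5 bp). Nr2f2, which specifies atrial identity, had 9346 bp (9043.5 ± 323 bp), Hey2, a Notch target of compact ventricular muscle, 8754 bp (8624 ± 28.3 bp), and Myocd, the coactivator of serum response factor, 6876 bp (6503 ± 67.9 bp). Isl1, a factor of second heart field precursors, had 4870 bp (4243.5 ± 494 bp). Of the 28 members 27 had a peak within 1 kb of the canonical start site. Mef2c had none there, at 13:83504034, and was marked at another annotated start. The list's median was 7530.5 bp (7203 ± 75.7 bp), above all 10000 random lists, whose central 95% ran from 1999.5 to 3039 bp. Distal H3K4me2, within 50 kb of the start site and over 2.5 kb from any protein-coding start, had a median of 8221.5 bp (7882 ± 339 bp) against 1078 bp in random lists. It reached 31718 bp (31502 ± 1.41 bp) around Gata4 and 29489 bp (28619 ± 1901 bp) around Hand2. The distal measure leaves out only bases within 2.5 kb of a start. The outer parts of broad domains that span a start site, as at Gata4, are therefore counted in it. Bases 2.5 to 5 kb from the start site can enter both the start-site and the distal measure.

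Genes of the contractile apparatus were marked although most of their promoters are poor in CpG. Of 28 sarcomere genes 27 had a peak at the start site, where random lists of matched CpG content had a median of 11. Actc1, the cardiac alpha-actin gene at 2:114052887, was covered over 9807 bp (9798 ± 91.9 bp) and Tnnc1, the cardiac troponin C gene at 14:31208312, over 8732 bp (8391 ± 164 bp). Myh7, the beta-myosin heavy chain gene at 14:54994626, had 8657 bp (8674 ± 123 bp), and Ldb3, a Z-disc gene at 14:34588664, had 7679 bp (7161 ± 666 bp). Tnni3, the cardiac troponin I gene, had 7037 bp (6684 ± 132 bp), Tnnt2, the cardiac troponin T gene, 7025 bp (6653 ± 187 bp), and Actn2, the alpha-actinin gene of the Z-disc, 5799 bp (5654.5 ± 168 bp). Myom2, which encodes an M-band protein, was the unmarked member: its nearest replicated peak lay 1158 bp away, and both replicates' own lists marked all 28 genes. The median was 6029 bp (5860.5 ± 109 bp) against 0.25 bp in random lists, above all 10000 of them. Distal coverage had a median of 5427.5 bp (4876 ± 721 bp), also above all random lists, and Myh6 and Myh7, neighbours on chromosome 14, each had 24631 bp of it.

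Genes of calcium cycling, conduction and natriuretic peptides were marked in 26 of 28 cases, against a random median of 17. Pln, the phospholamban gene at 10:53337693, was covered over 7993 bp (7452 ± 887 bp) and Slc8a1, the sodium-calcium exchanger gene at 17:81738377, over 7929 bp (7620 ± 298 bp). Jph2, which encodes a protein of the junction between sarcoplasmic reticulum and plasma membrane, had 6949 bp (6672 ± 36.8 bp). Gja1, the connexin 43 gene, had 6934 bp (6738 ± 218 bp). The calcium pump gene Atp2a2 had 6559 bp (6397.5 ± 239.7 bp), the ryanodine receptor gene Ryr2 5391 bp (5370.5 ± 9.19 bp), the pacemaker channel gene Hcn4 5360 bp (5000.5 ± 271 bp) and Nppa, which encodes atrial natriuretic peptide, 3124 bp (2613 ± 15.6 bp). Mb, the myoglobin gene, was marked only at another annotated start, and Sln, the sarcolipin gene, lay 20061 bp from the nearest peak. The median was 5329 bp (4889 ± 98.6 bp) against 1584 bp in random lists at the start site, and 4053 bp (3573 ± 683 bp) distally, above all 10000 random lists in both cases.

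**Figure D1:**
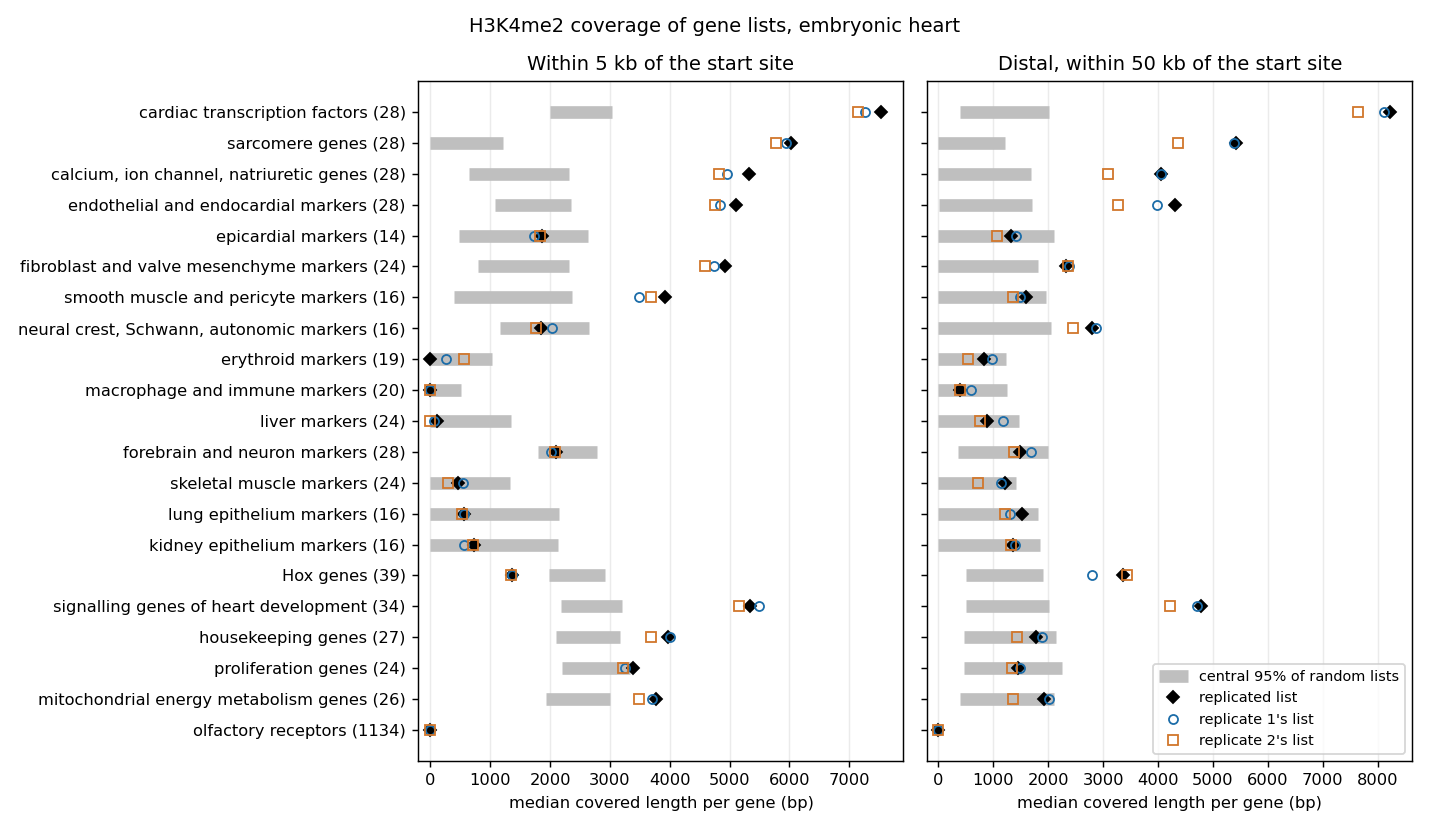
Median covered length per gene (bp) of each gene list, with the number of genes in brackets, within 5 kb of the start site (left) and distally within 50 kb (right); grey bars are the central 95% of 10000 random lists, diamonds the replicated list, circles and squares the replicates' own lists. The 3 heart muscle lists, at 7530.5, 6029 and 5329 bp, lie to the right of their grey bars at the start site.

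Other cell types of the heart differed among themselves. Of 28 endothelial and endocardial genes 25 were marked, with a median of 5108.5 bp (4796 ± 63.3 bp), above all random lists. Fli1, an ETS factor of endothelium, had 8535 bp, Dll4, a Notch ligand of arteries, 8417 bp, Npr3, a natriuretic peptide receptor of endocardium, 7992 bp and Mecom 7469 bp. Erg, another ETS factor, and Egfl7 were marked only at another start, and the nearest peak to the apelin receptor gene Aplnr lay 2891 bp away. All 24 fibroblast and valve mesenchyme genes were marked, with a median of 4920.5 bp (4664.5 ± 99.7 bp), above all random lists. Pdgfra, a growth factor receptor of fibroblasts, had 8773 bp, Sox9, a factor of valve mesenchyme, 7129 bp, Twist1 6586 bp and Prrx1 6030 bp. Smooth muscle and pericyte genes were marked in 15 of 16 cases, with a median of 3919.5 bp (3587 ± 146 bp), also above all random lists. Mcam had 6827 bp and Cspg4, a pericyte proteoglycan gene, 6274 bp, while Mylk, a myosin kinase gene, was unmarked. Distal medians were 4308.5 bp (3631 ± 508 bp) for endothelial genes, above all random lists, and 2316 bp (2374.5 ± 11.3 bp) at percentile 99.7 for fibroblast and valve genes, which lay at 95.4 within 100 kb. For smooth muscle and pericyte genes the distal median of 1600.5 bp (1427 ± 84.1 bp) lay at percentile 92.3, not above random lists. Des, the desmin gene, was a member of this list and of the sarcomere list.

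Epicardial markers were marked in 11 of 14 cases with a median of 1859 bp (1790 ± 71.8 bp), at percentile 67.3 of random lists. The transcription factor genes Wt1 and Tbx18 had 8884 and 6981 bp, while Msln, Muc16 and Upk3b, genes of the mesothelial surface, were unmarked. Markers of neural crest, Schwann cells and autonomic neurons were marked in 11 of 16 cases at percentile 46.2, with a median of 1855.5 bp (1897.5 ± 192 bp). Measured as the share of the gene body they lay at percentile 99.5. Hand2, which is also a cardiac factor of the list above, had the longest coverage, followed by the endothelin receptor gene Ednrb with 5256 bp. Dbh, an enzyme gene of noradrenaline synthesis, the myelin gene Plp1 and Phox2b were unmarked, and Sox10 was marked only at another start. Their distal median of 2802.5 bp (2666 ± 297 bp) lay at percentile 99.7, and at 93.3 with the better-scoring 50% of peaks. Among erythroid markers 8 of the 19 annotated were marked, and the median of 0 bp (410.5 ± 218 bp) lay at percentile 40.2. It was 565 bp at percentile 93.5 without replicate 1, 256 bp at 81.9 without replicate 2, and 725 bp at 93.2 in the pooled list. Tal1 had 6512 bp and Tfrc, also in the housekeeping list, 3910 bp. The globin genes Hba-a1 and Hbb-bs, named outside the fixed rule after their values were seen, had 0 bp. Macrophage and immune markers were marked in 2 of 20 cases, against a random median of 5, and their median of 0 bp lay at percentile 44.3. For this list and the erythroid list the random median was also 0 bp. A percentile of 0 bp then splits ties, so neither list could be called below matched random lists. Without CpG matching macrophage and immune markers lay below random lists, at percentile 0.630, as did erythroid markers at 1.35. Cd68, a macrophage gene, had 4028 bp (3802.5 ± 20.5 bp) in the window, with its nearest peak 2522 bp from the start site. Cd14 and Rag1 were marked, while Adgre1, Aif1, C1qa and C1qb, genes of tissue macrophages, had 0 bp around the start site.

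Signalling genes of heart development were all marked, 34 of 34, with a median of 5334.5 bp (5323 ± 229 bp), above all random lists at the start site and distally. Hes1, a Notch target, had 8732 bp, Smad7, an inhibitor of TGF-beta and BMP signalling, 8030 bp, the growth factor receptor gene Igf1r 7752 bp and the vascular growth factor gene Vegfa 7686 bp. The lists of housekeeping, mitochondrial energy metabolism and proliferation genes were marked without exception as well. The 27 housekeeping genes had a median of 3965 bp (3846.5 ± 235 bp) and the 26 genes of mitochondrial energy metabolism 3767 bp (3595 ± 164 bp), both above all random lists. Ubc had 7269 bp and Gapdh 6404 bp, while Idh2, a citrate cycle enzyme gene, had 7286 bp and Ppargc1a, a coactivator of mitochondrial genes, 5684 bp. The 24 proliferation genes had a median of 3394.5 bp (3244 ± 23.7 bp) at percentile 98.4, led by the cyclin genes Ccnd2 with 8444 bp and Ccnd1 with 6728 bp. Their call ended with a window of 10 kb, at percentile 87.7, and that of mitochondrial genes ended at percentile 96.7 when the share of the gene body was measured.

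Genes of other organs were not above random lists at the start site. Liver markers were marked in 7 of 24 cases (random median 10) with a median of 103 bp (34.0 ± 48.1 bp) at percentile 39.1, and skeletal muscle markers in 9 of 24 with a median of 465 bp (416.5 ± 172 bp) at percentile 63.9. Without replicate 1 these medians were 0 and 295 bp, without replicate 2 68 and 538 bp, and both were 0 bp with the better-scoring 50% of peaks. The serum albumin gene Alb and Ahsg had 0 bp, and the alpha-fetoprotein gene Afp 640 bp with no peak within 1 kb. The liver factor genes Foxa2 and Foxa3 were marked, with 4305 and 2521 bp. In the skeletal muscle list Mylpf, a myosin light chain gene of fast muscle, had the longest coverage, 4627 bp (4366 ± 462 bp), and was marked only at another start. Six1, Acta1 and Pax3 were marked with 3029, 2612 and 1747 bp, while the calcium pump gene Atp2a1, the calcium channel gene Cacna1s and the acetylcholine receptor genes Chrna1 and Chrng were unmarked. Lung epithelium markers were marked in 7 of 16 cases at percentile 34.9, with the factor genes Foxa1, Nkx2-1 and Sox2 among them and Cldn18, Lamp3, Napsa and Scgb1a1 unmarked. Kidney epithelium markers were marked in 7 of 16 at percentile 30.1: Podxl, Hnf1b, Six2 and Pax2 had 5401, 3178, 2701 and 2522 bp, and the water channel gene Aqp2 was unmarked. Forebrain and neuron markers, most of them with CpG-rich promoters, were marked in 25 of 28 cases, with a median of 2095.5 bp (2046 ± 44.9 bp) at percentile 31.6. Bcl11b had 5432 bp and Satb2 4558 bp, and Dcx, Neurod6 and Slc17a6 were unmarked. Distal coverage of these 5 lists lay between percentiles 79.6 and 94.4, though within 20 kb skeletal muscle reached 99.9 and lung 99.4. Lung also reached 98.6 within 100 kb, and kidney 98.1 with the better-scoring 50% of peaks. Without CpG matching liver markers lay below random lists at the start site, at percentile 0.880, and skeletal muscle markers at 2.305. Of 1134 olfactory receptor genes 4 were marked, against a random median of 109, a count below all random lists. By covered length this list and its random lists had medians of 0 bp, so that measure could not tell them apart. Olfr94 and Olfr56 were among them.

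Hox genes, which pattern the body axis, were marked in 31 of 39 cases, but coverage at their start sites was short. Hoxa2 and Hoxa1 had 5946 and 5394 bp and Hoxb2 and Hoxb4 3949 and 3685 bp, while Hoxb3, Hoxb8 and Hoxc11 were unmarked and Hoxb6 was marked only at another start. The median of 1358 bp (1355 ± 4.24 bp) lay below all 10000 random lists, whose median was 2381 bp. It lay at percentile 9.88 with a window of 10 kb, at 8.56 without CpG matching, and at 99.9 when the share of the gene body was measured, so the direction turned with the measure. Their distal median was 3360 bp (3118 ± 457 bp), above all random lists, and at percentile 97.2 within 20 kb. Clustered Hox genes share distal sequence, as Hoxa1 and Hoxa2 with 3922 bp each, so the members are not independent windows as in random lists.

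Cardiac regulators were among the genes with the broadest H3K4me2 domains, made by merging peaks within 1 kb. The broadest domain that held a protein-coding start site spanned 28133 bp at Gata4 (14:63228934–63257066), followed by 26015 bp at Hand2 (8:57311063–57337077). Then came 21751 bp at Lbh, a cofactor gene of limb and heart, 21026 bp at Nr2f2, 21002 bp at Meis2, a homeodomain factor gene, and 20859 bp at Qk, which encodes an RNA-binding protein. Myh7 had 20722 bp (14:54977767–54998488), Gata6 20243 bp, Nkx2-5 19420 bp (17:26835728–26855147) and Slc8a1 18672 bp. The next were Nfib, Josd2, Bahcc1, Smad7, Dll4, Tbx5, Tbx20, Igf2r, Irf2bp2 and Tnni3, from 18597 to 15324 bp. Of these 20 genes 10 belonged to the 3 heart muscle lists. Tnni3 held the last place by order of names: Tnnt1, outside these lists and named after its value was seen, shared its domain. Distal coverage within 50 kb was longest around Igf2r with 33991 bp (30489.5 ± 2256 bp), Gata4, Hand2, Qk with 26783 bp (22969.5 ± 4567 bp), Nfib with 26694 bp (24129.5 ± 3231 bp), Rbpms with 24879 bp, Myh6, Myh7, their neighbour Gm17428 and Btn1a1 with 24291 bp. The median protein-coding gene had 1892 bp around its start site and 734 bp distally.

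**Figure D2:**
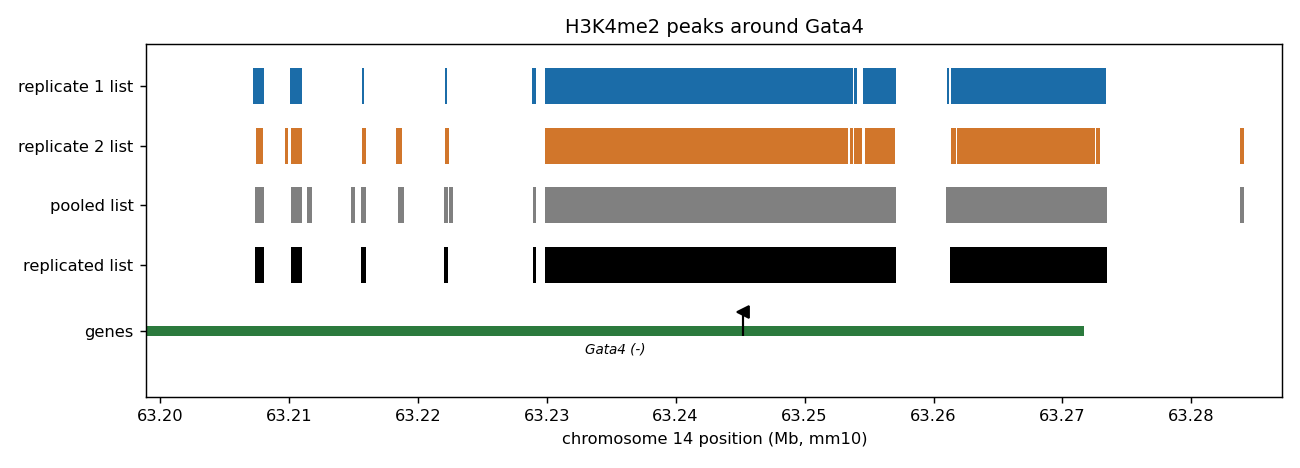
Peaks of the 4 lists (bars) between 63198934 and 63287066 on chromosome 14 (position in Mb, mm10), with Gata4 below and its canonical start site marked by an arrowhead that points along transcription. The domain of 28133 bp spans the start site in the replicated list. A second broad peak lies upstream of that start site, towards the right, and covers the 5' end of the annotated gene.

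Over the whole replicated list, 30177 of 50319 peaks on assembled chromosomes, 59.97%, were over 2.5 kb from every protein-coding start site. Among the better-scoring 50% of peaks 58.3% lay at promoters, within 1 kb of a start site. The distal peaks with the highest enrichment values, a scale set by the authors, were at 5:106573733–106575192 with 63.7 and at 10:120551367–120553763 with 63.2. The first had the starts of the lincRNA genes Gm28050 and Gm29464 within 1 kb. The nearest coding genes were Gm17304 at 34.6 kb and Hmga2, a growth regulator, at 76.1 kb. Others of the strongest 10 lay inside Lin28b, an RNA-binding protein gene of early development (10:45485204–45487141, 59.2), and 102.9 kb from Irx5, a homeodomain factor gene of the heart (8:92460000–92461317, 56.5). The remaining 6 had values from 56.1 to 61.6 and lay nearest to Prr7, Cd247, Gm4952, Cldn9, Otub1 and Rpgrip1. Those nearest to Cd247 and Gm4952 also had a noncoding start within 1 kb. The observed to expected CpG ratio within these 10 peaks ran from 0.470 nearest to Cd247 to 1.14 inside Lin28b, and was 0.912 nearest to Irx5. Whether any of them is a promoter missing from the annotation was not tested.

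Several sequence motifs of cardiac factors were more frequent in distal domains than in nearby sequence of the same GC content. The MEF2 motif, bound by Mef2 factors of muscle, was found in 14.0% of 22484 windows of 500 bp (exact 95% interval 13.6 to 14.5%) and in 5.31% of control windows (5.03 to 5.62%). The ratio was 2.63 (2.52 ± 0.0365). Ratios were 2.06 (1.97 ± 0.134) for the ETS motif of endothelial and general factors, 1.56 (1.503 ± 0.0565) for TEAD, the motif of Hippo pathway factors, and 1.31 (1.32 ± 0.00275) for FOX. They were 1.26 (1.25 ± 0.0131) for NKX2, 1.17 (1.15 ± 0.00240) for GATA and 1.15 (1.13 ± 0.0319) for AP-1. CTCF, a comparison motif whose factor acts in all tissues, had the highest ratio in this setting, 4.67 (4.35 ± 0.149). OCT, another of the 7 comparison motifs, had 1.39 (1.30 ± 0.0302), so a share above control was not specific to heart motifs. Intervals overlapped control for SRF at 1.15, SOX at 1.04, HNF1 at 1.38, HNF4 at 0.852, NEUROD at 1.12, PU.1 at 1.09 and REST at 1.03. SRF was above control in both replicates' own lists, at 1.198 and 1.196, in 1 kb windows at 1.14 and in whole distal peaks at 1.21. HNF1, SOX, NEUROD and PU.1 were also above control under some alternatives. TBX at 0.721 (0.737 ± 0.0205) and HAND at 0.929 (0.943 ± 0.00719) were below control. The HAND consensus, CATCTG, lies on the opposite strand within that of NEUROD, CAGATGGC, so its matches are not specific to Hand factors. Without GC matching the ratio turned for GATA, at 0.970, and for OCT, at 0.894, the calls of NKX2 at 1.04 and FOX at 1.05 ended, and MEF2 fell to 1.44. In the better-scoring 50% of peaks NKX2 at 1.12 and AP-1 at 1.00 also lost their calls, and in windows of 200 bp MEF2 had 3.99 and CTCF 1.78. The comparison motif HNF1 had 2.375 in windows of 200 bp, above CTCF and ETS, at low shares of 0.163% and 0.0686%. ETS exceeded MEF2 in the better-scoring 50%, at 3.04 against 2.69, and without GC matching, at 2.65. The ETS consensus, ACCGGAAR, contains a CpG, and control windows were matched on GC content but not on CpG content. How far CpG content accounts for the ETS ratio was therefore not tested.

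**Figure D3:**
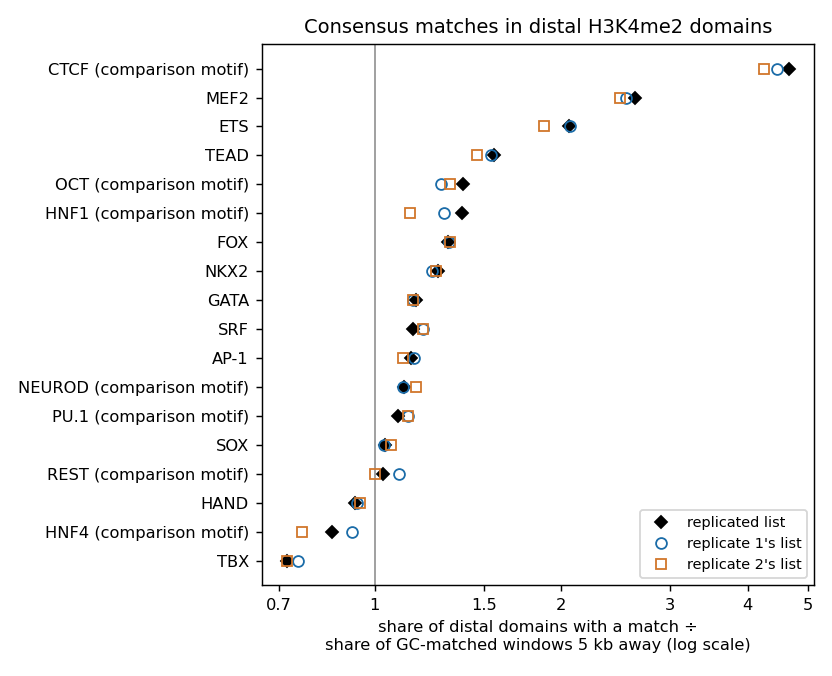
Ratio, on a log scale, of the share of distal domain windows with a consensus match to the share in GC-matched windows 5 kb away, for 18 motifs; diamonds are the replicated list, circles and squares the replicates' own lists. In this setting MEF2 has 2.63, ETS 2.06 and CTCF 4.67; their order changes under some alternatives.

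At promoters, the mark followed CpG content. Of 21911 protein-coding genes 14555 had a peak within 1 kb of the start site, 66.4% (66.5 ± 0.297%). The share rose from 2.51% of the genes with the most CpG-poor promoters, the lowest decile, to 99.6% of the highest decile. Promoters held 31.3% of replicated peaks (28.3 ± 3.41%), against a median of 2.65% over 100 shifts of the peaks along each chromosome. Exons held 5.62% (5.75 ± 0.275%), introns 33.7% (36.9 ± 1.90%) and intergenic sequence 29.5% (29.1 ± 1.78%), where shifted peaks had 58.6%. Promoter peaks had a median width of 1893 bp and other peaks 664 bp. Among noncoding genes the mark was found at 41.8% of antisense, 21.6% of lincRNA and 19.3% of microRNA genes, and at 3.79% of processed pseudogenes. Away from coding start sites the shares were 18.6, 16.4, 10.1 and 3.18%.

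The replicates marked nearly the same genes. Both lists marked 14458 genes, replicate 1 alone 163 and replicate 2 alone 71. Among the genes of replicate 1 alone, Osbpl5, Gm11444, Lrg1, Nhlh2 and Dbx2 had the strongest promoter peaks, and among those of replicate 2 alone Nin, Ltk, Fth1, Glyctk and Gm17428. For 39 of the 163 and 25 of the 71 the other list had a peak within 2.5 kb of the start site. At Osbpl5 the covered length was 2991.5 ± 139 bp in the replicates' own lists, and at Nin 2823.5 ± 241 bp. Of replicate 1's peaks 72.6% had a counterpart in replicate 2 and of replicate 2's 86.8% had one in replicate 1, where shifted lists reached at most 3.42 and 3.93%. With each list ranked by the authors' p value and divided into 10 equal parts, the strongest 3 parts of both lists were shared in full. In the weakest part 21.7% of replicate 1's peaks and 50.04% of replicate 2's were shared.

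**Figure D4:**
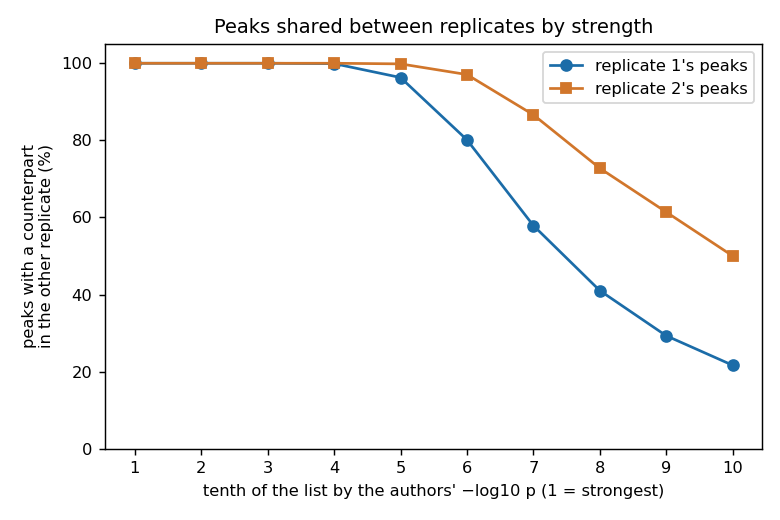
Share of each replicate's peaks (%) with a counterpart in the other replicate, in 10 equal parts of the list from the strongest (1) to the weakest (10) by the authors' p value. The share falls from 100% to 21.7% for replicate 1 (circles) and 50.04% for replicate 2 (squares).

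The authors' replicated list was a subset of the pooled list, 80.4% of it, with the same positions and values. All 44890 pooled peaks with an overlap of at least 50% in both replicates were kept, and 5440 more were kept without one. The 12256 peaks left out had a median width of 248 bp, against 877 bp for those kept. Of these, 6506 had a counterpart in replicate 1 only, 2431 in replicate 2 only and 3319 in neither.

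The X chromosome carried fewer peaks than any autosome. It had 6.79 replicated peaks per Mb, against an autosome median of 20.3 and a lowest autosome, chromosome 14, of 15.2. The ratio to the autosome median was 0.334 (0.335 ± 0.00714). On X 52.0% of protein-coding genes were marked, against a median of 69.2% and a lowest value of 54.0% among autosomes. From autosomal genes of the same CpG deciles 556 marked X genes would be obtained, and 493 were observed.

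**Figure D5:**
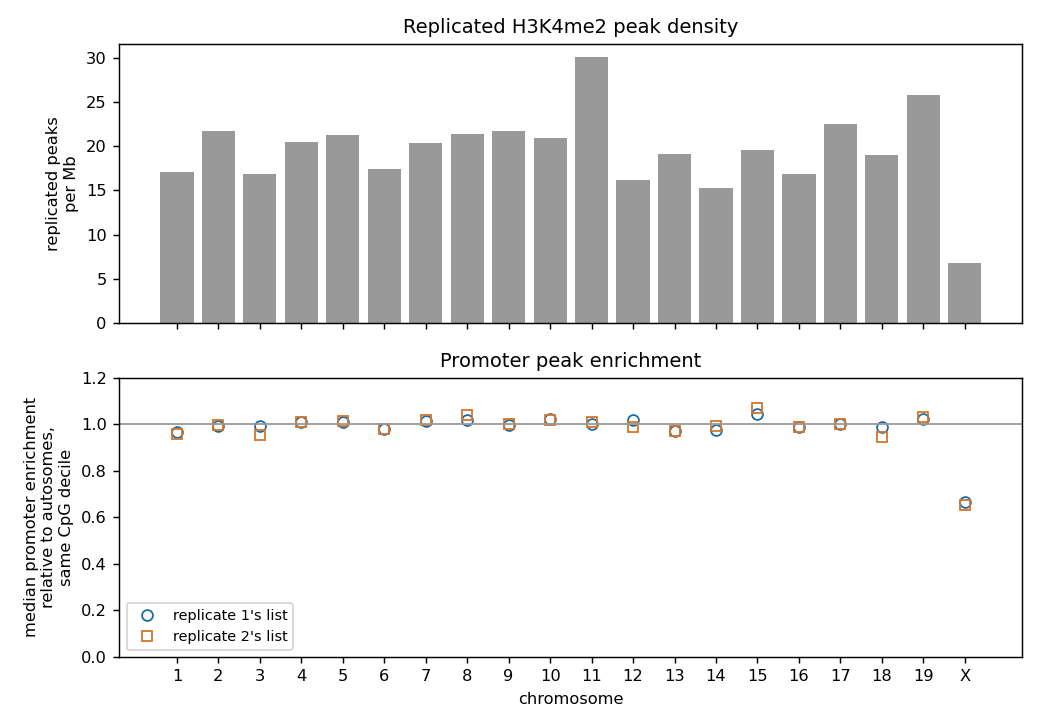
Replicated peaks per Mb for each autosome and X (top), and median enrichment value of promoter peaks relative to autosomal promoters of the same CpG decile in each replicate's list (bottom, circles and squares). X has 6.79 peaks per Mb, and the autosomes lie between 15.2 and 30.0.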

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

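The replicated list held 11 peaks on contigs that are not placed in the assembled chromosomes, which no comparison of gene lists, motifs or chromosomes used. They are given because they lie in sequence outside the main comparisons, and no expected number was available to set them against. Of these, 4 lay on a contig assigned to X and 4 on contigs assigned to chromosome 4.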

How the results depend on the processing

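The motif windows under 10% repeat sequence were chosen after the motif results were seen, and the other alternatives before the data were examined. The count of gene lists above random lists was 9 to 11 at the start site and 8 to 10 distally over the alternatives, and the 3 heart muscle lists lay above the random range in every alternative run. The count of motifs above control was 7 to 12. Values that moved by more than their bound follow. The bound was the replicate spread, except for the kept share, where it came from the exact binomial 95% interval over peaks. In the ranges without 1 replicate below, the promoter share of 30.7% and the marked genes of 66.3% lay within the spread. With the better-scoring 50% of peaks, replicate 1's overlap became 83.9%, replicate 2's 98.2% (70.4% with a reciprocal overlap of 50%), the pooled peaks kept 83.4%, the promoter share 58.3%, the marked genes 63.5% and the X ratio 0.435. The kept share was 72.1% with any overlap of 1 bp, 62.1% with a reciprocal overlap of 50%, and 77.2 to 88.8% without 1 replicate. These alternatives recount overlaps with the replicates, unlike the authors' selection, which kept 80.4%. The same recount with an overlap of 50% of either peak in both replicates gave 71.7%. The promoter share was 34.7% with a window of 2.5 kb, 35.6% with all transcript starts, 25.7% in the pooled list and 25.8 to 30.7% without 1 replicate. Marked genes were 65.5% with 500 bp, 68.3% with 2.5 kb, 68.5% with all transcript starts, 67.0% in the pooled list and 66.3 to 66.7% without 1 replicate. The X ratio was 0.354 by covered bases and 0.326 in the pooled list. The direction reversed for Hox genes with the share of the gene body (percentile 99.9), and for the GATA (0.970) and OCT (0.894) motifs without GC matching; AP-1 stood at 1.00 in the better-scoring 50%, which was counted as a lost call and not as a reversal after the value was seen. The cause was not tested. Of the other values, 428 kept their side of the threshold, 24 passed it, 11 no longer did, 3 reversed and 2 moved. Values without a call could still change side of the random median or of control. Under 10% repeat sequence TBX stood at 0.761 and HAND at 0.896, still below control. Read depth, which the files do not give, limits what the weakest peaks can show.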

Other observations

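The tests of peaks per gene on X, of the strength of unshared peaks, of erythroid cells and macrophages in replicate 1 and of other organs' promoters were chosen after the results they address were seen, as were the noncoding and CpG-poor genes named here and the Y-linked genes. The other tests were written before their values were seen, apart from the ratio over 7 lists together, which was not planned.

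Noncoding genes were also marked broadly. The domain of 26015 bp at Hand2 held the starts of the lincRNA genes 5033428I22Rik and Gm34030. Neat1 and Malat1, lincRNA genes expressed in nearly all tissues, lay in domains of 12081 and 9968 bp, and Carmn, a lincRNA gene of cardiac and smooth muscle, in 8635 bp. A domain of 9569 bp (2:180384879–180394447) held Mir1a-1, a microRNA gene of heart and skeletal muscle 54.3 kb from the start of Gata5, and the lincRNA gene B230312C02Rik. Mir132 and Mir212 shared a domain of 11521 bp, which also held the start of the coding gene Hic1, and Mir322, Mir351 and Mir503 shared 7706 bp on X.

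Among genes with CpG-poor promoters, the lowest 3 deciles, 743 of 6574 were marked, 11.3%. Sarcomere genes of these deciles were marked in 15 of 16 cases, fibroblast and valve mesenchyme genes in 6 of 6 and calcium and ion channel genes in 7 of 8. Skeletal muscle markers were marked in 1 of 12 and macrophage markers in 1 of 15. The longest coverage was at Tbx5 and Actc1, then at Kdm6b, a histone H3K27 demethylase gene, with 9762 bp (9679 ± 98.99 bp, SD, n = 2), and at Tnnt1, a troponin T gene, with 9080 bp (8637.5 ± 172 bp). The start of Tnnt1 lay in the domain of 15324 bp that also held the start of Tnni3, and the windows of both genes overlap. Unc45b, a myosin chaperone gene, had 7748 bp (7229 ± 55.2 bp). On the Y chromosome 9 peaks lay nearest to Uba1y, Kdm5d, Eif2s3y, Uty and Ddx3y.

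Peak density on X was lower than on every autosome. Fewer genes on X did not account for all of it, since X had 1.23 replicated peaks per protein-coding gene and the lowest autosome 1.46. Repeats and gaps did not account for all of it either: X had 13.3 peaks per Mb of sequence outside repeats and gaps, and the lowest autosome 24.03. The ratio of X to the autosome median was 0.334 per Mb, 0.489 per gene and 0.415 per Mb outside repeats and gaps. Each may thus account for a part, and their joint effect was not tested. A candidate explanation is that 1 active X per cell carries the mark. Promoter peaks on X had a median enrichment of 0.660 ± 0.0102 (SD, n = 2) relative to autosomal promoters of the same CpG decile, and autosomes lay between 0.946 and 1.07. This is a hypothesis, since the scale of the enrichment is not stated and fewer X copies in male cells were not separated from it.

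Replicate 1's list held 17308 peaks without a counterpart and replicate 2's 7452. Weak peaks near the calling threshold stay open as an explanation: 98.6% of replicate 1's unshared peaks lay in the lower-scoring 50% of its list, but so did 99.9% of replicate 2's. For cells of another tissue in replicate 1, 0 of 7 lists of other tissues' genes had unshared distal peaks at least 2 times as frequent in replicate 1 as in replicate 2, with intervals that did not overlap. That bound, set beforehand, could not decide over all 7 lists, since counts per list were 2 to 27 and interval bounds of the ratio reached 5.25. For erythroid and macrophage markers the upper bounds were 1.11 and 1.95. These were the only lists with a bound below 2 and were singled out after the results were seen. Their bounds therefore do not decide, and each of the 7 lists, taken singly, stays open.

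Some regulators of other organs were marked in heart, such as Foxa2 and Pax2. Others of the same lists, such as Hnf1a, Hnf4a and Myf5, named after their values were seen, were not. Cells of other organs in the dissected hearts would bring peaks at those organs' promoters of lower CpG content. Here 24 of 76 members of 5 lists in the lower 5 CpG deciles were marked, against a random median of 29. Random genes of these deciles were themselves often marked, up to 86.8% in decile 5. A count below their median therefore cannot exclude such cells. Of the 32 members in the upper 5 deciles 96.9% were marked, and random genes of the same deciles gave 30 to 32 marked. Since nearly all genes of these deciles carried the mark, this count could not test whether CpG-rich promoters carry it in any tissue, and that stays open.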
